A study of Homo sapiens with 12 samples.

How the data were processed

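GRO-seq measures nascent RNA: nuclei are isolated, RNA polymerases already on the DNA extend their transcripts in a run-on reaction, and that RNA is sequenced. The series holds 12 GRO-seq libraries of nuclear RNA from 3 human cancer cell lines: HCT116 (colorectal), MCF7 (breast) and SJSA (osteosarcoma). Cells received 10 µM Nutlin, a small molecule that blocks the binding of MDM2 to p53, or 0.2% DMSO, its solvent, for 1 h. Each of the 6 groups has 2 libraries, numbered 1 and 2. The labels also give every library a batch, 1 or 2, equal to its replicate number. They do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

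The authors deposited 1 table per cell line with whole-number counts per gene, 1 RefSeq transcript per gene symbol, not normalized. Every sample column was matched to its library by the name its label gives, and 0 sample columns were left unused. Per the submitters' processing notes, FastQC 0.11.2, CASAVA, Bowtie2 2.2.3, SAMtools 0.1.19, Picard 1.129 and deepTools 2.2.2 were used with genome build GRCh37 (hg19). Duplicate reads were kept, per the names of the deposited files. The counting tool, the counted part of each gene, the use of strand and the rule by which a table lists genes are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart. Each table has 2 rows whose name is no gene; they hold 0% of the counts and were left out. The tables list different genes: 15130 for HCT116, 14193 for MCF7 and 15879 for SJSA. A symbol found in all 3 tables was taken as 1 gene, which gives 13020 of 17193 symbols and 82.9% to 90.3% of each library's counts; 12332 of them are listed with the same transcript in every table.

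Total counts per library run from 11008759 to 48677204. The counts of paired libraries in every group differed by more than sampling noise: chi-square per degree of freedom ran from 7.14 to 224. Counting error alone is therefore much smaller than the spread between libraries. Each library was counted as its own replicate, though this spread does not show that the libraries came from separate cultures.

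The counts were tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. All 12 libraries entered 1 quasi-likelihood fit with a mean per group, TMM normalization and the edgeR expression filter, which kept 10736 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were Nutlin against DMSO in each line, the average Nutlin effect (a fit of cell line plus treatment), the difference of the Nutlin effect between lines (a joint test and each pair of lines), genes higher in all 3 lines, and the DMSO level of each line against the mean of the others (10062 genes with the same transcript). Log2 fold changes are Nutlin over DMSO, given ± standard error, the absolute log2 fold change divided by the root of F. Levels are CPM, counts scaled to library size over the genes tested, given as mean ± SD. Overlaps of called genes were tested by a one-sided Fisher's exact test. The cell lines share no control libraries, but the fit shares each gene's estimate of the spread between them. A gene with a small error can therefore pass in several lines, so calls in different lines are not independent.

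The labels give same-numbered libraries the same batch, so the replicate numbers were taken to pair the libraries. They do not say that the libraries of a batch were handled together. Deviations of same-numbered libraries from their group means correlated across genes at 0.56 in HCT116, -0.14 in MCF7 and -0.27 in SJSA, which gives no sign of pairing in MCF7 and SJSA. With batch as the tested term in a fit of each line alone, 2585 of 12806 genes differed between batches in HCT116, 26 of 11500 in MCF7 and 3 of 13208 in SJSA. The fit with the replicate number as a block within each line is called the blocked fit, and its value stands beside a result where it changes the call or moves a count by over 1.5 times.

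Gene lists were fixed before the data were examined, from general knowledge: 6 lists of p53 targets and their union, the p53 family, G2/M genes, G1/S and replication genes, MYC targets, immediate early genes, heat shock genes, ATF4 and unfolded protein response genes, NF-kB targets, interferon response, histone, ribosomal protein and housekeeping genes, estrogen-induced genes, 12q13-q15 genes, and markers of epithelial, breast luminal, intestinal, mesenchymal and bone, and blood and endothelial cells. Lists with at least 5 tested members were tested by camera in edgeR with a preset correlation of 0.01, two-sided, adjusted over the lists and cell lines. Camera with an estimated correlation and fry were alternatives. Camera tests a list against other genes and fry against no change. The members of 5 lists were also counted, after the data were seen, among the genes differing in DMSO level, where the 6 tests of the 2 lists with at least 5 members were adjusted together. The genes named in the text follow a rule written before the data were examined: TP53, MDM2, MDM4, CDKN1A and PPM1D; the genes of largest change in each comparison among those called with a mean of at least 20 counts and no overlap between the libraries compared; and the leading members of each list. The same rule was applied, after the data were seen, to the blocked fit and to genes outside the shared set. Genes named outside this rule are said to be so.

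Alternatives were other normalizations, other filters on low counts (none, or a CPM of at least 1 in 2 libraries), DESeq2 1.42.0, each cell line fitted alone, the replicate block and leaving out each library in turn. Added after the data were seen were fits of each line over every gene of its own table, genes with the same transcript in all tables only, crossed replicate numbers, the MCF7 and SJSA libraries alone, and each batch alone. In the fits that leave a group with 1 library, that library is assumed to vary like the others. Without a block, a difference between batches also enters the Nutlin comparison of that line.

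The scripts were tested on simulated counts with known changes, drawn from the means and spread of the blocked fit and the libraries' own sizes. Replicate blocks were thus built into the counts, which favours the blocked fit in the recovery rates below. Of 4-fold changes in HCT116 the unblocked fit recovered 89.4%, whereas it called 0 genes in the real HCT116 libraries. Of genes changed by 2-fold in HCT116, MCF7 and SJSA, 46.3%, 49.3% and 40.3% were recovered by the unblocked fit and 92.5%, 86.6% and 82.1% by the blocked one. The average effect recovered 94.0% and 98.5%. Of the unchanged genes, the unblocked fit called 0 in each of these 4 comparisons, and the blocked fit called 9, 9 and 6 in the lines and 9 on average. With each line fitted alone, 0, 1 and 2 unchanged genes were called in HCT116, MCF7 and SJSA, and 3, 11 and 11 with the block. The joint test of a difference between lines, with genes changed in HCT116 alone, recovered 3.0% without and 71.6% with the block at 2-fold, with 0 and 6 false calls. Of 100 unchanged lists of 20 genes in HCT116, 2 passed camera with the preset correlation, 0 with an estimated correlation and 4 passed fry. These lists were tested with the block, and their genes were simulated independently. They therefore do not test the preset correlation for lists whose members move together. In the fit of the average effect the estimated correlation was 0.35 for all p53 targets and 0.82 for the G1/S genes. Gene relations (overlap, antisense, host gene) come from RefSeq genes on GRCh38.p14, another build than the tables use, so no coordinates are given.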

Results

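Nascent transcription was measured by GRO-seq in HCT116, MCF7 and SJSA cells after 1 h of Nutlin or DMSO, with 2 libraries in each of the 6 groups (n = 2 throughout). Nutlin frees p53, a transcription factor activated by stress, from its inhibitor MDM2. Total counts were 14687711 and 37839265 in the HCT116 DMSO libraries and 47634428 and 40390658 in the HCT116 Nutlin libraries. They were 11064211 and 13766906 for MCF7 DMSO, 11132966 and 11008759 for MCF7 Nutlin, 15548387 and 48677204 for SJSA DMSO and 19231151 and 15801152 for SJSA Nutlin. The 10 genes with the most counts held 2.48% to 3.96% of a library. MDM2 alone held 1.62% and 1.38% of the counts of the SJSA Nutlin libraries. Genes are named by symbol, without coordinates. Differences between replicates had an SD across genes of 0.67 (DMSO) and 0.61 (Nutlin) on the log2 scale in HCT116, against 0.28 and 0.31 in MCF7 and 0.29 and 0.28 in SJSA.

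The average Nutlin effect over the 3 cell lines asks which genes changed transcription within 1 h across these lines. Known p53 target genes led the rises. FAS, a death receptor, rose by 2.56 ± 0.26 on the log2 scale (adjusted p = 0.00023), BTG2, an antiproliferative factor, by 2.33 ± 0.19 (adjusted p = 4.8e-05) and MDM2, which p53 itself induces, by 2.31 ± 0.27 (adjusted p = 0.00059). KLHDC7A (2.38 ± 0.40) and UNC5B-AS1 (2.28 ± 0.34), neither on the p53 target list, completed the 5 largest rises. UNC5B-AS1 overlaps UNC5B, so that their reads cannot be told apart. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 2.24 ± 0.34 (adjusted p = 0.0050). TP53 itself, with a log2 change of -0.02 ± 0.11, and MDM4, another inhibitor of p53, with 0.12 ± 0.07, did not pass the test. Of 10736 genes tested in edgeR, 71 rose and 2 fell, and 920 had an unadjusted p under 0.05. With the replicate number as a block, 117 rose and 21 fell. In the MCF7 and SJSA libraries alone, a fit chosen after the data were seen because the HCT116 libraries varied most, 157 rose and 67 fell, and all 71 risers were among them. Fitted in the same way within each batch, 57 rose and 5 fell in batch 1 and 96 rose and 9 fell in batch 2, including 55 and 66 of the 71. These fits reuse libraries from which the 71 were chosen, so such overlap is no independent support.

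Of 89 p53 targets on the list, 68 were tested, 34 of them rose on average and none fell. Adjusted over the list alone, 54 rose and 1 fell, and 45 rose in the blocked fit. Their median log2 change was 0.81, and 64 of 68 lay above 0. Among cell cycle arrest genes, 5 of 9 rose, with CDKN1A and BTG2 first, then PLK3 by 0.93 ± 0.10 and GADD45A by 0.89 ± 0.16. The call of GADD45A ended without HCT116 DMSO 1 (0.83), MCF7 DMSO 1 (0.82), MCF7 DMSO 2 (0.79) or MCF7 Nutlin 2 (0.84). Of apoptosis genes, 6 of 13 rose, among them FAS, TP53INP1 (2.08 ± 0.33), BAX (1.64 ± 0.12), which permeabilizes the mitochondrial outer membrane, and the death receptor TNFRSF10B (1.31 ± 0.14). Of genes in negative feedback on p53, 4 of 6 rose: MDM2, CCNG1 (1.33 ± 0.16), TRIAP1 (1.25 ± 0.18) and PPM1D (1.23 ± 0.14), a phosphatase that acts on p53. Of DNA repair genes, 8 of 9 rose, led by RPS27L (1.96 ± 0.16), DDB2 (1.47 ± 0.09), a damage sensor of nucleotide excision repair, RRM2B (1.42 ± 0.15) and the polymerase POLH (1.35 ± 0.19). Of metabolism and autophagy genes, 5 of 13 rose, led by SESN1 (2.26 ± 0.23), FDXR (2.22 ± 0.22), SESN2 (1.73 ± 0.26) and C12orf5 (1.61 ± 0.18), also called TIGAR. Of signalling and other targets, 6 of 18 rose, led by the cytokine GDF15 (2.17 ± 0.33), PHLDA3 (1.86 ± 0.21), HSPA4L (1.5 ± 0.21) and CYFIP2 (1.43 ± 0.22). All p53 targets together were higher than other genes by camera (p = 2.2e-149 with the preset correlation, adjusted p = 0.00096 with an estimated correlation), and each of the 6 sublists kept its call with an estimated correlation. Within batches, the median of the 68 targets in HCT116 was 1.30 and 0.68, in MCF7 0.75 and 0.80, and in SJSA 0.73 and 0.58.

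**Figure D1:**
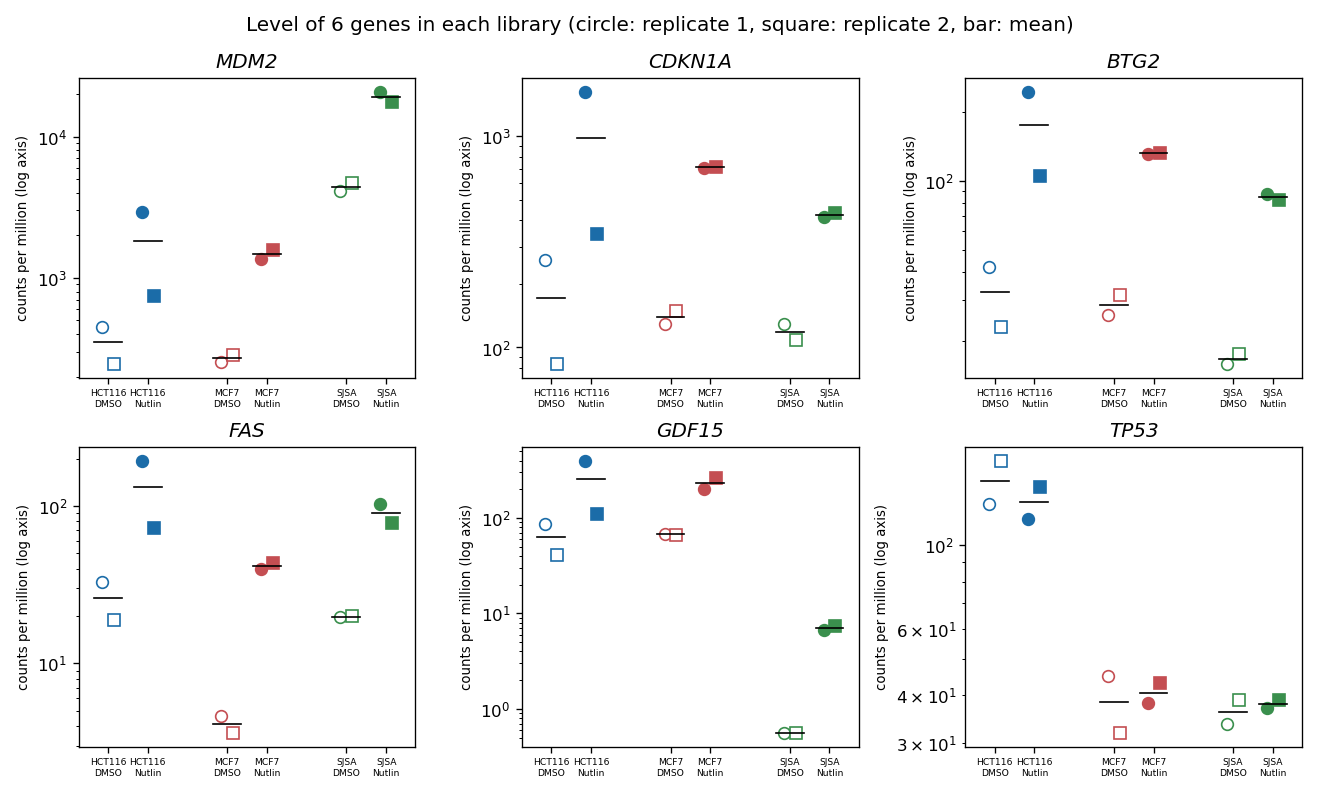
CPM, counts scaled to library size (log axis), of MDM2, CDKN1A, BTG2, FAS, GDF15 and TP53 in each library, by cell line and treatment; circles are replicate 1, squares replicate 2 and bars the mean of 2 libraries. The MCF7 and SJSA Nutlin libraries lie above their DMSO libraries for every gene shown but TP53, while the HCT116 replicates lie far apart, as for MDM2 after Nutlin (1825 ± 1528 CPM).

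The 2 genes that fell on average were LAG3, an immune checkpoint receptor, with -0.61 ± 0.12 (adjusted p = 0.031), and COL18A1, a collagen, with -0.39 ± 0.08 (adjusted p = 0.029). The call of LAG3 ended without any library but HCT116 DMSO 1, HCT116 DMSO 2 and HCT116 Nutlin 2, that of COL18A1 without any but MCF7 DMSO 2, MCF7 Nutlin 1 and SJSA DMSO 2, and both in each batch alone, with log2 changes from -0.52 to -0.66 for LAG3 and from -0.36 to -0.44 for COL18A1 over all libraries left out. In the blocked fit the largest falls were in small nucleolar RNAs, which guide RNA modification: SNORD79 (-0.78 ± 0.11, adjusted p = 0.00082), SNORD100 (-0.74), SNORD10 (-0.72), SNORD47 (-0.71) and SNORD87 (-0.63). SNORD79 and SNORD47 overlap GAS5, itself among the called genes. Of the p53 family, 3 members were tested and 0 passed over all genes (TP73 at -0.37 ± 0.10), and 1 fell adjusted over the list alone. G1/S genes (median -0.21, 21 of 21 below 0) and G2/M genes (median -0.14, 22 of 24 below 0) were lower by camera with the preset correlation, which ended with an estimated correlation (adjusted p = 0.51 and 0.55), and 0 members of either list fell in edgeR or its blocked fit. The immediate early genes, which growth signals switch on within minutes, were lower in the blocked fit alone (adjusted p = 0.0047, and 0.14 with an estimated correlation): NR4A1 fell by 0.44 ± 0.09 and CTGF by 0.43 ± 0.09, while ATF3, a stress-induced transcription factor that is also on the list, rose by 0.90 ± 0.12. The 12q13-q15 genes, whose 1 riser was MDM2, were higher than other genes by camera in the blocked fit (adjusted p = 0.024, and 0.11 with an estimated correlation) and not without the block (adjusted p = 0.21), where fry called them higher than no change (adjusted p = 0.015). Lists of MYC targets, heat shock, ATF4, NF-kB, interferon, histone, ribosomal protein, housekeeping and epithelial genes were not called on average, although the ribosomal protein gene RPS19 rose by 0.46 ± 0.09 in the blocked fit.

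In HCT116, a colorectal carcinoma line, the 2 replicates lay far apart. MDM2 went from 349.5 ± 147 CPM in DMSO to 1825 ± 1528 after Nutlin and CDKN1A from 172 ± 125 to 980.7 ± 899. BTG2 (2.44 ± 0.36), BAX (1.36 ± 0.20), DDB2 (1.21 ± 0.14) and XPC (1.02 ± 0.15) came closest to the threshold, with adjusted p from 0.053 for DDB2 to 0.061 for the others. In edgeR 0 genes passed, 666 had an unadjusted p under 0.05 (439 higher), and DESeq2 called 79 higher and 3 lower. The blocked fit called 128 higher and 26 lower: BTG2 rose by 2.36 ± 0.16, CDKN1A by 2.34 ± 0.16, FAS by 2.24 ± 0.18, SESN1 by 2.15 ± 0.21, MDM2 by 2.14 ± 0.22 and RPS27L by 1.95 ± 0.17. Its falls included the small RNAs SCARNA6 (-1.65 ± 0.38), SNORD10 (-0.99 ± 0.21) and SNORA63 (-0.91 ± 0.22), the replication genes MCM5 (-0.86 ± 0.19) and CDC45 (-0.77 ± 0.19), and TNFRSF13C (-1.23 ± 0.30). EGR1, an immediate early gene, fell by 1.10 ± 0.21 there, and ATF3 rose by 0.94 ± 0.18. Leaving out HCT116 Nutlin 2 or DMSO 2 without a block sets a lone batch 1 library against libraries of both batches. The batch difference then enters the Nutlin comparison: EGR1 was at -4.60 without Nutlin 2 and at 2.18 without DMSO 2.

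In HCT116, 0 of the 68 p53 targets passed over all genes, 50 rose adjusted over the list alone, and 47 rose in the blocked fit; 65 lay above 0, with a median of 1.15. As a list they were higher than other genes by camera (p = 1.5e-77 with the preset correlation, adjusted p = 0.014 with an estimated correlation), and so was each sublist. By fry, which tests the list for a change of its own and not against other genes, they rose (adjusted p = 0.049). With an estimated correlation the metabolism sublist lost its call (adjusted p = 0.071), and in the blocked fit the negative feedback sublist did (adjusted p = 0.076). All 21 G1/S genes (median -0.42) and all 24 G2/M genes (median -0.36) lay below 0, called lower by camera with the preset correlation. That call ended with an estimated correlation (adjusted p = 0.27 and 0.28), and 0 members passed singly. In the blocked fit 2 G1/S genes fell over all genes (MCM5 and CDC45), and 17 G1/S and 12 G2/M genes fell adjusted over the list alone. The difference lay mostly in batch 1, where the medians were -0.90 and -0.65, against -0.11 and -0.08 in batch 2. The ATF4 and unfolded protein response genes were higher (9 of 10 above 0, adjusted p = 0.0028), a call that ended with an estimated correlation (adjusted p = 0.24), with medians of 0.42 and 0.12 within batches. The 5 epithelial markers tested were higher in the blocked fit alone (adjusted p = 0.0085, and 0.15 with an estimated correlation).

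In MCF7, a breast carcinoma line, 10 genes rose and 0 fell. FAS rose most, by 3.35 ± 0.47, from 4.13 ± 0.74 to 41.7 ± 2.76 CPM. BAX rose by 1.91 ± 0.21, CCNG1 by 1.81 ± 0.26, DDB2 by 1.68 ± 0.15 (adjusted p = 0.0026), GADD45A by 1.58 ± 0.16, AEN by 1.19 ± 0.15 and XPC by 1.14 ± 0.15, all p53 targets. The other 3 were SLC12A4 (1.77 ± 0.20), a potassium-chloride cotransporter, TYMS (0.88 ± 0.12), thymidylate synthase, and TYMSOS (1.64 ± 0.21), which overlaps TYMS, so that their reads cannot be told apart. MDM2 (2.44 ± 0.51, from 270.6 ± 21.9 to 1469 ± 157 CPM) and CDKN1A (2.36 ± 0.62, from 139 ± 13.5 to 712 ± 5.12 CPM) did not pass in the fit of 12 libraries, where the spread of the HCT116 replicates entered their error, and rose in the blocked fit (adjusted p = 9.0e-07 and 3.2e-08). For the 0 falls, 74 genes were lower at an unadjusted p under 0.05, DESeq2 called 45 higher and 0 lower, and the blocked fit 73 higher and 2 lower. Those 2 were MYC (-0.77 ± 0.14) and PDLIM7 (-0.83 ± 0.16), an actin-associated protein. In the blocked fit FOSL1, an immediate early gene, rose by 1.42 ± 0.18. The MCF7 libraries fitted alone gave 124 higher and 13 lower, and those of MCF7 and SJSA together 117 and 9. Without MCF7 DMSO 1 or MCF7 DMSO 2, 0 genes passed, without MCF7 Nutlin 1 and 2, 2 and 1 did, and without SJSA DMSO 1 or 2, 5 did. Without HCT116 Nutlin 1 or 2, 46 and 47 passed, and without HCT116 DMSO 1 or 2, 18.

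In MCF7, 7 of 68 p53 targets rose over all genes, 34 adjusted over the list alone and 31 in the blocked fit, and 61 lay above 0 (median 0.76). The list was higher than other genes by camera (p = 5.6e-105 with the preset correlation, adjusted p = 0.011 with an estimated correlation), and its 6 sublists were called with either correlation. By fry, set against no change, the list rose (adjusted p = 0.049). The MYC targets were lower with the preset correlation (12 of 16 below 0, adjusted p = 0.029), a call that ended with an estimated correlation (adjusted p = 0.17), with medians of -0.22 and 0.03 within batches. The immediate early genes were called lower in the blocked fit (adjusted p = 0.0094, and 0.18 with an estimated correlation), with medians of -0.28 and -0.37 within batches. The 12q13-q15 list was called higher there (adjusted p = 0.010, and 0.15 with an estimated correlation), with MDM2 as its 1 riser. Without the block 9 of its 16 members lay above 0 and 7 below, with a median of 0.03.

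In SJSA, an osteosarcoma line with high MDM2 transcription, 4 genes rose, all p53 targets: BAX by 1.65 ± 0.20 (adjusted p = 0.018), DDB2 by 1.51 ± 0.15, AEN, a nuclease, by 1.30 ± 0.15, and XPC, a repair factor, by 1.25 ± 0.15. MDM2 went from 4413 ± 409.7 to 19038 ± 2287 CPM (2.11 ± 0.50) and CDKN1A from 119 ± 14.8 to 423 ± 13.2 CPM (1.83 ± 0.61); both passed in the blocked fit (adjusted p = 5.4e-06 and 5.2e-07) and not without it. The blocked fit also called GDF15 (3.68 ± 0.31, from 0.561 ± 0.005 to 7.09 ± 0.49 CPM), FDXR (2.59 ± 0.17), TP53INP1 (2.50 ± 0.18), BTG2 (2.34 ± 0.17) and ATF3 (1.08 ± 0.19) higher. MIR3189 (2.85 ± 0.40), also higher, overlaps GDF15. The ribosomal protein gene RPS19 rose by 0.68 ± 0.14. In edgeR 0 genes fell, 48 were lower at an unadjusted p under 0.05, and DESeq2 called 28 higher and 2 lower. The blocked fit called 47 higher and 3 lower, the latter LOC102577426 (-1.56 ± 0.29), SNORD20 (-1.54 ± 0.33) and CTC1 (-1.05 ± 0.17), a telomere maintenance protein. SJSA fitted alone gave 86 higher and 20 lower, and with MCF7 78 and 12. Without any 1 of the SJSA libraries 0 genes passed, and without MCF7 DMSO 1 or 2, 1 did; without HCT116 Nutlin 1 or 2, 29 and 30 did, and without either HCT116 DMSO library 8.

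In SJSA, 4 of 68 p53 targets rose over all genes, 32 adjusted over the list alone and 28 in the blocked fit, and 60 lay above 0 (median 0.60). The list was higher than other genes by camera (p = 1.1e-107, adjusted p = 0.011 with an estimated correlation). By fry, set against no change, it missed the threshold (adjusted p = 0.051). Its 6 sublists were called with either correlation. The immediate early genes were called lower in the blocked fit alone (adjusted p = 0.044, and 0.27 with an estimated correlation). Lists not named for a line were not called in it.

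**Figure D2:**
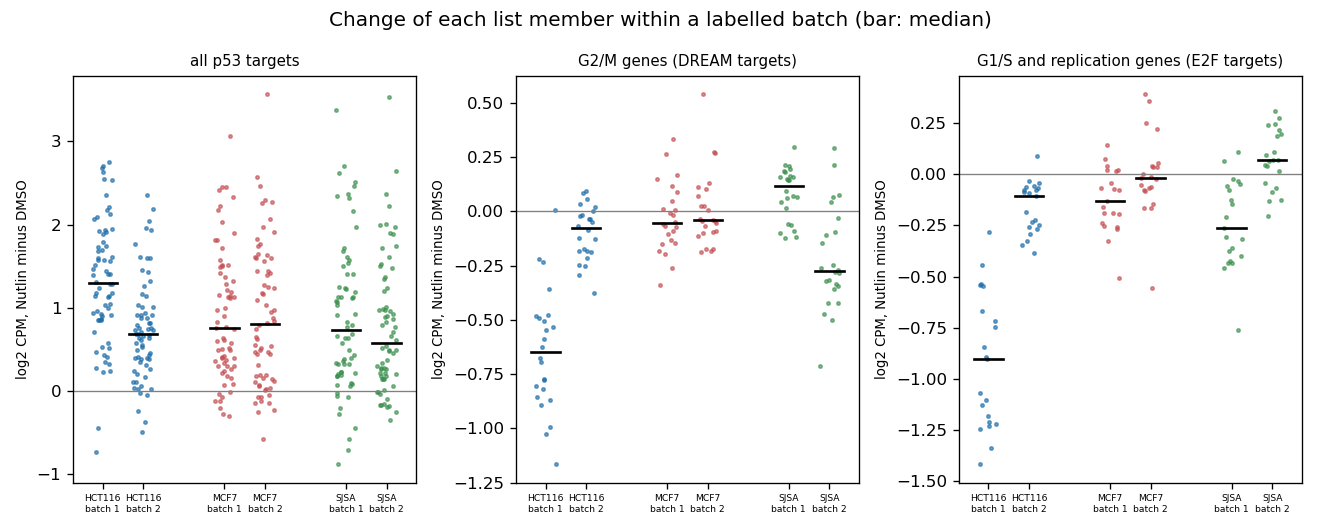
Nutlin minus DMSO in log2 CPM for each member of 3 lists (all p53 targets, G2/M and G1/S genes), within batch 1 and batch 2 of each cell line; each point is a gene and the bar is the list's median. The median of the p53 targets lies above 0 in all 6 pairs of libraries (0.58 to 1.30), though single members lie below 0, and the medians of the cell cycle lists are lowest in the batch 1 pair of HCT116.

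Genes outside the shared set were tested in each line alone. In HCT116, where a fit without the block called 0 of 12806 genes (152 at an unadjusted p under 0.05, and DESeq2 called 8), the blocked fit called 46 of 2214 such genes higher and 1 lower. A blocked fit of a line's 4 libraries leaves a single residual degree of freedom, so its errors lean on the spread pooled over genes. ACTA2 (2.52 ± 0.22), which overlaps FAS, GJB5 (2.53 ± 0.63), TNFRSF10C (1.97 ± 0.26), a decoy receptor, PRDM1 (1.76 ± 0.24) and ZMAT3 (1.67 ± 0.20), a p53-induced RNA-binding protein, were higher, and RHBDL3 fell by 0.77 ± 0.21. In MCF7 without a block, 20 of 1142 rose and 3 fell, among them TNFRSF10C (3.34 ± 0.23), EDA2R (2.79 ± 0.15) and SPATA18 (2.77 ± 0.14), with falls of MYEOV (-0.75 ± 0.16), RBBP8NL (-0.68 ± 0.12) and EPPK1 (-0.53 ± 0.10). In SJSA 29 of 2740 rose and 14 fell, led by NHLH2 (3.68 ± 0.33), TRIM22 (2.44 ± 0.15), EDA2R (2.18 ± 0.14), ZMAT3 (1.55 ± 0.14) and PRDM1 (1.55 ± 0.20), with falls of DDIT4L (-1.34 ± 0.33), SHF (-1.14 ± 0.20) and GBP2 (-0.86 ± 0.17). With the block SJSA gave 23 and 5, and MCF7 23 and 8.

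Whether the response differed between lines was tested directly. In edgeR the joint test called 0 of 10736 genes, with 114 at an unadjusted p under 0.05, and each of the 3 pairs of lines gave 0, with 223 (HCT116 and MCF7), 166 (HCT116 and SJSA) and 32 (MCF7 and SJSA) at an unadjusted p under 0.05. MDM2 differed by -0.05 ± 0.68 between HCT116 and MCF7, 0.28 ± 0.68 between HCT116 and SJSA and 0.33 ± 0.68 between MCF7 and SJSA, within its error. The blocked fit called 0 genes in the joint test (384 at an unadjusted p under 0.05) and 1 in each of 2 pairs. HMGCS1, an enzyme of sterol synthesis, had a lower log2 change in HCT116 than in MCF7 by -1.26 ± 0.20 (adjusted p = 0.0497), and SLC12A4 a higher one in MCF7 than in SJSA by 1.51 ± 0.24 (adjusted p = 0.036). The joint test of DESeq2 called 3 genes. GADD45A had log2 changes of 0.90 ± 0.16 in HCT116, 1.58 ± 0.19 in MCF7 and 0.29 ± 0.16 in SJSA, SLC12A4 of 0.52 ± 0.21, 1.76 ± 0.24 and 0.25 ± 0.20, and ITGA3, an integrin, of 0.98 ± 0.15, 0.15 ± 0.15 and 0.02 ± 0.15. On counts simulated from the blocked fit, which favour that fit, the joint test in edgeR recovered 3.0% of 2-fold changes confined to HCT116, and 71.6% with the block. Smaller differences were thus mostly not detectable with 2 libraries per group.

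Genes higher in every line were counted to find a response common to the 3 lines. In edgeR 0 genes passed in all 3, since 0 passed in HCT116; the 4 risers of SJSA (AEN, BAX, DDB2 and XPC) were also risers of MCF7 (one-sided Fisher's exact test, p = 3.8e-13). DESeq2 gave 21. In the blocked fit 36 genes were higher in all 3 lines, of which 25 were on the p53 list. If calls in the lines were independent, 0.0038 would be expected, but the lines share each gene's estimate of the spread. BTG2 (2.2), MDM2 (2.11), FAS (2.17), UNC5B-AS1 (2.08), KLHDC7A (2.08) and SESN1 (2.04) had the largest changes in their lowest line. The 11 not on the list were ANXA4, BLOC1S2, C17orf82, FAM212B, FBXO22, IKBIP, KLHDC7A, MIR3189, PGPEP1, PTP4A1 and UNC5B-AS1, named because all 11 are counted. MIR3189 overlaps GDF15, which is on the list, and UNC5B-AS1 overlaps UNC5B, so these need not be separate responses. Of the 128 blocked risers of HCT116, 91.4% had a log2 change above 0 in MCF7 and 94.5% in SJSA; of the 73 of MCF7, 91.8% did in HCT116 and 98.6% in SJSA; and of the 47 of SJSA, all did in both. Among all genes the share was 48.9% to 52.95%. Pairs of lines shared 51 (HCT116 and MCF7), 42 (HCT116 and SJSA) and 37 genes (MCF7 and SJSA), with a one-sided Fisher's exact p of 1.8e-85, 1.3e-78 and 4.6e-76. The Fisher p-values of this paragraph take the calls of 2 lines as independent, so they do not allow for the shared estimate of the spread. The shares with a log2 change above 0 need no call in the second line.

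**Figure D3:**
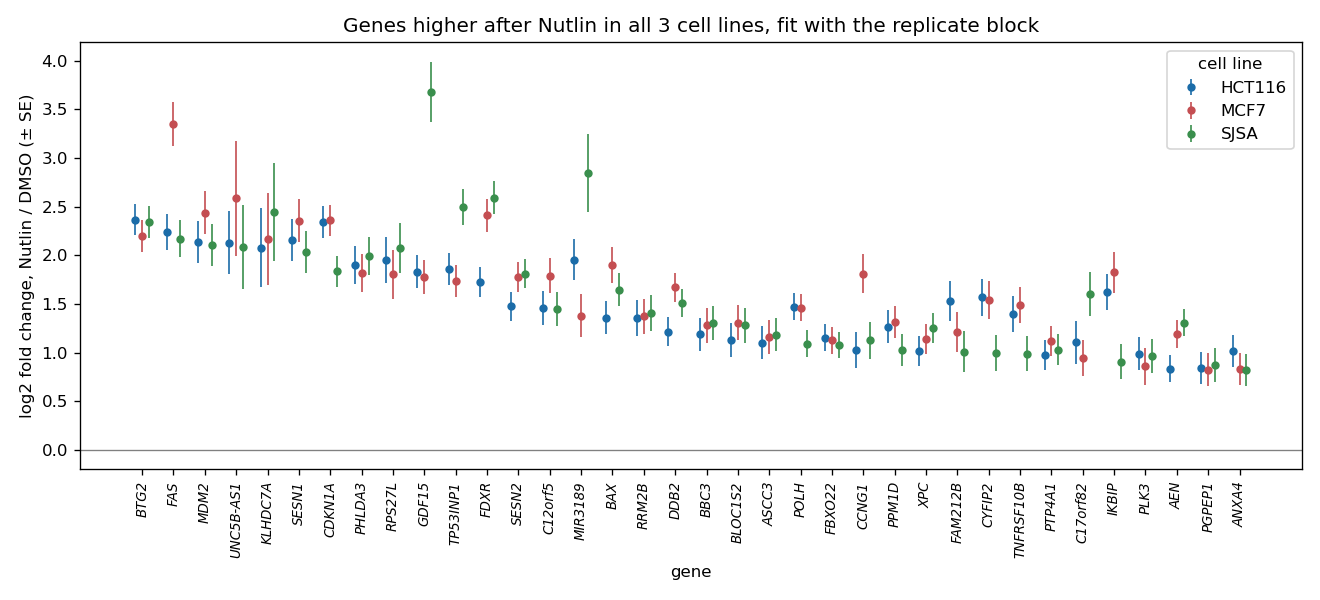
Log2 fold change of Nutlin over DMSO (± SE) in HCT116, MCF7 and SJSA for the 36 genes higher in all 3 lines in the blocked fit. FAS, BTG2 and MDM2 exceed 2 in every line, and GDF15 (3.68) in SJSA has the largest change shown.

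The DMSO libraries were compared to describe the lines before treatment. Of 15 genes of 12q13-q15, a region often amplified in sarcomas, 9 were higher in SJSA, 2 lower (CPSF6 and YEATS4, named because both are counted) and 4 not called. The list was higher than other genes by camera (p = 4.2e-13 with the preset correlation, adjusted p = 0.0015 with an estimated correlation), a test chosen after the data were seen. The 63 p53 targets compared were not called as a list in any line. MDM2 was at 4413 ± 409.7 CPM against 349.5 ± 147 in HCT116 and 270.6 ± 21.9 in MCF7, CDK4 at 689 ± 15.1 against 50.7 and 37.6, OS9 at 931 ± 26.7 against 36.8 and 59.1, and CTDSP2 at 1383 ± 76.8 against 59.3 and 147. Their log2 differences from the mean of the other lines were 3.84 ± 0.41 for MDM2, 3.98 ± 0.11 for CDK4, 4.32 ± 0.14 for OS9, 4.28 ± 0.27 for AVIL and 3.89 ± 0.17 for CTDSP2. GDF15 was at 0.561 ± 0.005 CPM in SJSA, against 63.1 ± 31.8 and 67.2 ± 0.32. All 4 epithelial markers compared, of 15 on the list, were lower in SJSA: the keratin KRT18 was at 21.8 CPM there against 122 in HCT116 and 591 ± 71.2 in MCF7, and the transcription factor ELF3 at 1.26 against 64.3 and 145. NPPB (99.8 ± 10.9 CPM) and HIST1H4L (53.2 ± 7.99 CPM) were among the genes highest in SJSA over the other lines, all under 1 CPM. In MCF7 both breast luminal markers compared, of 11 on the list, and all 4 estrogen-induced genes compared, of 10, were higher: FOXA1 was at 254 ± 43.3 CPM against 2.03 and 2.07, TFAP2C at 212 ± 29.98 against 6.03 and 23.1, XBP1 at 393 ± 55.0 against 65.1 and 35.9, and NRIP1, a nuclear receptor cofactor, at 1039.9 ± 58.0 against 196 and 209. Among p53 targets, MCF7 had high ULK1 (326 ± 28.3 CPM against 26.5 and 49.3) and low GPX1 (3.61 ± 0.10 against 58.4 and 52.5), and HCT116 high KITLG (1689 ± 378 CPM against 96.2 and 45.5). OR51I1 (29.7 ± 2.02 CPM) and OR51B4 (16.4 ± 4.16 CPM), of the olfactory receptor cluster, had counts in HCT116 alone. Of 10062 genes with the same transcript in all tables, 5248 differed in HCT116 from the mean of the other lines, 5189 in MCF7 and 5306 in SJSA (edgeR). Because the lines' tables list different genes, 4 of 10 estrogen-induced genes and 2 of 11 breast luminal markers could be tested for the Nutlin effect, 1 blood and endothelial marker, and none of the intestinal and the mesenchymal and bone markers; in these lists 0 genes passed. In the tables of single lines, 0 members of these lists passed either except 1 mesenchymal and bone marker lower in SJSA, which was 0 with the block. Without MCF7 DMSO 1 or 2, 3488 and 3450 genes differed in MCF7, and without SJSA DMSO 2, 3529 differed in SJSA.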

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

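The cell cycle lists were chosen for weighing after their results were seen, and the tests of their explanations before, except the comparison of the 2 batch pairs for the cell cycle state. The difference of the Nutlin effect between 2 cell lines brought each of these results here. The G2/M genes had a lower Nutlin effect in HCT116 than in MCF7 (camera p = 2.4e-09 with the preset correlation) and than in SJSA (p = 1.5e-07), and so had the G1/S and replication genes (p = 6.5e-09 and 8.4e-09). With an estimated correlation, 0 of these differences passed (adjusted p = 0.91 for each). Within the batch 1 and batch 2 pairs, the G2/M medians were -0.65 and -0.08 in HCT116, -0.05 and -0.04 in MCF7 and 0.12 and -0.27 in SJSA. In batch 2 SJSA was thus lower than HCT116. The G1/S medians were -0.90 and -0.11 in HCT116, -0.13 and -0.02 in MCF7 and -0.26 and 0.07 in SJSA. Tests of 4 explanations argue against level and length of the members and do not decide on depth. The HCT116 batch 2 pair, of near-equal depth, had a median of -0.090 over the 45 members (SE across members 0.019, 38 of 45 lower). The same members had -0.071 and -0.037 in the MCF7 pairs and -0.048 and -0.065 in the SJSA pairs. The batch 2 pair thus shows little difference between lines and does not decide on depth. The HCT116 batch 1 pair had -0.80 after thinning to the same total (SE across members 0.049, 45 of 45 lower). Thinning keeps each gene's expected share of a library, so this median could hardly move. It therefore does not decide on depth either. Of 10000 random lists matched on level and length, 0 had a median as low as the observed -0.43 (mean -0.0072, lowest -0.15). This gives a permutation p of 1e-04, the smallest they can give. Genes of like level and length thus did not fall as the members did. The random genes were drawn singly and lack the members' correlation, so this p does not measure the spread between libraries. What stays open beside depth is a cell cycle state that varied between cultures. The members' median differed by 0.80 between the 2 HCT116 Nutlin libraries, more than the Nutlin change, against 0.27 between the 2 DMSO libraries. The pairs thus disagreed (-0.77 in batch 1 and -0.09 in batch 2). A varying cell cycle state remains a candidate explanation beside an effect of Nutlin itself.

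By camera with the preset correlation, the cell cycle arrest genes among the p53 targets had a higher Nutlin effect in HCT116 than in SJSA (p = 9.0e-05) and in MCF7 than in SJSA (p = 0.00019). With the same correlation, all p53 targets together did in HCT116 against SJSA (p = 0.00051) and in MCF7 against SJSA (p = 0.0052), and the negative feedback genes did in MCF7 against SJSA (p = 0.0042). With that correlation the effect on ATF4 and unfolded protein response genes was higher in HCT116 than in MCF7 (p = 4.3e-05) and lower in MCF7 than in SJSA (p = 0.00067), and that on epithelial markers was higher in HCT116 than in MCF7 (p = 0.0025). With an estimated correlation 0 of the 60 tests passed (adjusted p at or above 0.84, and at or above 0.63 with the block).

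In single genes, HMGCS1 differed between HCT116 and MCF7 (-1.26, blocked fit) and SLC12A4 between MCF7 and SJSA (1.51, blocked fit), and the joint test of DESeq2 called GADD45A (adjusted p = 0.016), SLC12A4 (adjusted p = 0.016) and ITGA3 (adjusted p = 0.024). Without the block edgeR called 0 genes in these tests, with 32 to 223 at an unadjusted p under 0.05 in the pairs of lines.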

How the results depend on the processing

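The fits on the MCF7 and SJSA libraries alone, each batch alone, every gene of each table, genes with the same transcript and crossed replicate numbers were chosen after the data were seen. Of the counts of genes or lists, 256 stayed within 1.5 times the value reported and 109 did not; of the values of named genes, 3261 kept their direction and side of the threshold, 649 newly passed, 103 no longer passed and 17 reversed. The list test of all p53 targets in each line kept its direction and stayed under an unadjusted p of 0.05 in all 69 values over the settings, fry included, where the adjusted p in SJSA missed the threshold (0.051). Where a cause is not given by the setting's own construction, the cause was not tested.

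With the replicate block, HCT116 had 128 genes higher and 26 lower, MCF7 73 and 2, SJSA 47 and 3, the average effect 117 and 21, and 36 genes were higher in all 3 lines; beside these and the calls named with the comparisons it changed no other call of a comparison. With numbers crossed in MCF7 and SJSA, counts were 124 and 28, 65 and 1, 44 and 8, 148 and 67, with 1 gene in the joint test and 31 higher in all 3 lines. DESeq2 gave 79 and 3 in HCT116, 45 higher in MCF7, 28 and 2 in SJSA, 16 lower on average, 3 in the joint test and 21 higher in all 3 lines. Each line alone gave 124 and 13 in MCF7, 86 and 20 in SJSA and 1 lower for the mean of the 3 effects; with all its own genes it gave 142 and 11 (MCF7) and 119 and 39 (SJSA), and with the block 165 and 41 (HCT116), 176 and 55 (MCF7) and 92 and 16 (SJSA), with 47 higher in all 3. The MCF7 and SJSA libraries alone gave 117 and 9, 78 and 12 and on average 157 and 67, and turned the TP53 average to 0.072. Batch 1 alone gave 5 lower on average, and batch 2 alone 9, with TP53 at 0.043. Without a filter on low counts, 8 genes were higher in HCT116, 16 in MCF7, 7 in SJSA and 5 in all 3. With total counts only, the CPM filter or the same transcript, 1 gene was higher in HCT116 and 1 in all 3 lines. In HCT116, 6 lists were called with an estimated correlation, with and without the block, against 10; fry called 4 in HCT116, 3 in MCF7 (against 8) and 1 in SJSA (against 7).

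Leaving out each library in turn, which assumes that the lone library left varies like the others, gave 0 to 402 higher and 0 to 327 lower in HCT116, 0 to 47 higher in MCF7, 0 to 30 higher in SJSA, 0 to 13 lower on average and 0 to 27 in all 3 lines. Without HCT116 DMSO 2 the average falls were 13 and without HCT116 Nutlin 2 12; without MCF7 DMSO 1, MCF7 Nutlin 2, SJSA DMSO 1 or SJSA Nutlin 1 they were 0. Genes differing in DMSO level ranged from 3450 to 5742 in MCF7 and from 3529 to 5874 in SJSA. Directions of values that had not passed turned for KRT8 (-0.15 to 0.75), KRT18 (-0.30 to 0.94), CLDN4 (-0.14 to 1.6), MDM4 (-0.038 to 0.27), EGR1 (-4.60 to 2.18) and TP53 (-0.37 to 0.017) in HCT116, TP53 in MCF7 (-0.15 to 0.35) and SJSA (-0.038 to 0.18), and on average TP53 (-0.086 to 0.059) and NR4A1 (-0.96 to 0.036). Because these fits have no block, the HCT116 counts and values above mix the batch difference with the Nutlin effect.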

Other observations

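The lists of sterol synthesis and actin genes, the tests of the immediate early genes between batches, the list test of all small nucleolar RNAs, the test of their host genes and the splits of the libraries were chosen after the results were seen.

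In the blocked fit of MCF7, genes of sterol and fatty acid synthesis were among the risers outside the p53 list: HMGCS1 (1.04), MSMO1 (0.92), SCD (0.87), ACAT2 (0.85), FDFT1 (0.85) and SQLE (0.74). INSIG1 (0.79), MVK (0.65) and FDPS (0.62) missed the threshold (adjusted p = 0.056, 0.075 and 0.13). These were noticed in the data, so the hypothesis that sterol synthesis genes rise as a group was tested on 13 other members, of which IDI1 (0.73) and LSS (0.63) rose. All 13 lay above 0 in MCF7, with a median of 0.45 and of 0.43 and 0.44 within the batches (p = 0.0028, camera with an estimated correlation). That correlation was -0.035 for these 13, against 0.20 for the 9 noticed before, so the p takes the 13 as uncorrelated. By the same test with an estimated correlation, 12 of 13 lay above 0 in SJSA (median 0.18, p = 0.031) and 9 of 13 below 0 in HCT116 (median -0.10, p = 0.31), and MCF7 was higher than HCT116 (p = 0.0039) and than SJSA (p = 0.0079). A rise of the whole group in MCF7 is thus a hypothesis, found and tested on the same libraries.

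Of 11 actin and SRF target genes noticed in the data, 9 lay below 0 in MCF7 in the blocked fit, among them PDLIM7 (-0.83), which passed, ZYX (-0.78), CTGF (-0.75), TAGLN (-0.71) and TPM1 (-0.59), while FHL2 (0.11) and TPM2 (0.03) did not. In HCT116, 7 of the 11 lay below 0 (p = 0.998, camera with an estimated correlation) and FHL2 rose by 0.95. On 7 other members, taken in the same way, all 7 lay below 0 in MCF7 (median -0.32, within batches -0.50 and -0.14) and in SJSA (median -0.28), but the list missed the threshold (p = 0.11 in MCF7 and 0.077 in SJSA, camera with an estimated correlation), as it did in HCT116 (6 of 7 below 0, median -0.17, p = 0.45, with the same correlation estimate), so a fall of this group stays open.

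The HCT116 libraries differed between batches at 2585 of 12806 genes, 1378 higher and 1207 lower in batch 2. Thinning all 4 libraries to the smallest of their totals left 2473, so the count does not rest on the extra counts of the deeper libraries. Thinning keeps each gene's expected share of a library, so other effects of depth were not tested. Removing the trend with gene length left 2546, so length does not account for the bulk. The immediate early genes were higher in batch 2 (median 1.44, p = 0.0499 with an estimated correlation, 0.71 adjusted over 20 lists), among them EGR1 (4.29), EGR3 (4.84), CTGF (3.47), CYR61 (3.10) and NR4A1 (2.89), with 14 of 16 called higher. Over the libraries of both treatments, the p53 targets were lower in batch 2 (median -0.58, 44 of 80 called lower and 4 higher) and the G1/S genes higher (median 0.67, 18 of 21 called higher), neither called as a list with an estimated correlation (p = 0.36 and 0.37). The fit of these 4 libraries leaves a single residual degree of freedom. The correlation it estimated, 1 for the G1/S genes and -0.05 for the immediate early genes, is therefore not usable. The p-values of these 3 lists decide nothing. A candidate explanation, left undecided by these p-values, is that the cultures of the batches differed in growth stimulus. Since the labels give no more on the batches, no cause beside depth, length and growth stimulus was tested.

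In HCT116, 11 of 254 small nucleolar RNAs fell in the blocked fit (median -0.91), while their 11 host genes had a median of -0.16 (SE across genes 0.058), 0 of them called. These 11 were picked for their fall, so this does not exclude lower host transcription for them. Over all 244 with a host tested, the median was -0.35 (SE across genes 0.028), against -0.022 (SE across genes 0.014) for their 139 hosts. Of these hosts 0 were called lower, and 189 of the 244 lay below their host. In these libraries this argues against lower host transcription as the whole cause of the fall over all of them. The SEs take genes as separate, though many share a host, and do not measure the spread between libraries. Over all 254 the median was -0.33 in HCT116, -0.21 in MCF7 and -0.28 in SJSA, lower than other genes in HCT116 (p = 0.039) and SJSA (p = 0.032) and missing the threshold in MCF7 (p = 0.12), by camera with an estimated correlation. These p-values are unadjusted, and the list holds the 11 called lower in HCT116 and the 1 called lower in SJSA. They therefore rest partly on genes already seen to fall. The median differed by 0.94 between the 2 HCT116 DMSO libraries, more than the Nutlin change, but by 0.70 in the same direction between the 2 Nutlin libraries. Such a shift shared by a batch is removed in the blocked fit and does not account for the fall: the median within pairs was -0.27 and -0.40 in HCT116, -0.42 and 0.02 in MCF7 and -0.41 and -0.14 in SJSA. Whether short RNA was recovered unevenly between the 2 libraries of a pair stays open, since 2 pairs do not decide it, and the pairs were compared after the result was seen. No biological explanation beside host transcription was tested.

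The average effect was also counted on 100 of the 462 splits of the 12 libraries. Of these 1, the real one, gave as many as its 73 genes, and the highest of the others gave 6. The 9 other splits that part all pairs of replicates, which differ from the real one in exchanging treatments within a pair, gave at most 0 genes, and the 17 that follow the HCT116 batches gave 0 to 6. Only splits that part all pairs keep the pairing of the libraries, and 9 others of that kind are too few to exclude chance.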
